A study of Mus musculus with 25 samples.

How the data were processed

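Cortex RNA of 25 male mice was sequenced, 5 mice in each of 5 groups: wild type (C57BL/6J) and transgenic mice of an amyloid model (B6C3) on vehicle, vestitol, salviolone or both. Per the labels, libraries were made from total RNA, and a TruSeq RNA kit and a SMARTER mRNA-Seq kit are both named. Per the labels, the authors trimmed adapters with Trim Galore and aligned reads with STAR to mm39. Versions, the counting tool, strand setting and annotation are not given in the sources used here. The authors deposited a table of raw counts per gene and a table of FPKM, and both hold the same 25 samples. The FPKM were checked against the counts: the gene length they imply varied between samples with a median coefficient of variation of 0.177%. The count table holds 21720 genes, of which 2769 were at 0 in every sample. Of values from 4 to 39, 44.3% were multiples of 4, against 25% by chance. How the authors' counting gave this is not stated, and the test was repeated on counts divided by 4. Intervals and tests rest on the spread between mice.

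Total counts per library ran from 59376320 to 109776852. Thus 3 counts, the limit that a count of 0 allows, correspond to 0.0273 to 0.0505 CPM. Where the authors' table counts a fragment more than once, these limits would be higher. Such limits cover counting error only. Genes were kept by edgeR's filterByExpr by group (minimum count 10), which left 16515 genes with 99.99% of all counts. TMM factors were 0.980 to 1.04, and the common dispersion 0.0483. All 25 samples entered 1 fit with 1 coefficient per group in edgeR 4.0.16 (R 4.3.3) and were tested with the robust quasi-likelihood F test, two-sided. P values were adjusted with Benjamini-Hochberg within each comparison, with calls at an adjusted p under 0.05. The 8 comparisons were the model control against wild type, each treatment against the model control, the combination against each compound and against the mean of both, and vestitol against salviolone. Printed CPM use TMM-scaled library sizes.

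There were 40 gene lists with 722 gene names, 719 of them in the table: transgene check, plaque-associated microglia, homeostatic microglia, reactive astrocytes, complement, interferon response, antigen presentation, inflammatory cytokines and NF-kB targets, immediate-early genes, excitatory synapse, inhibitory neurons, cholinergic system, amyloid processing and clearance, tau and tau kinases, autophagy and lysosome, mitochondrially encoded, nuclear oxidative phosphorylation, ribosomal proteins, antioxidant response, unfolded protein response, heat shock, cholesterol synthesis, glucocorticoid-responsive, circadian clock, calcium signalling, myelinating oligodendrocytes, oligodendrocyte precursors, astrocytes, pan-neuronal, endothelium, mural cells, choroid plexus, ependyma, meninges, blood cells, striatum, hippocampus, thalamus, hypothalamus and basal forebrain and strain-variable between C57BL/6J and C3H. Lists, comparisons, tests, the rule for named genes and most alternatives were chosen before the data were examined. The 39 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a comparison. List scores are means of log2 CPM (prior count 2) of the list genes. Some list genes are also expressed in cortex neurons, so the tissue lists are no pure markers. Named genes were, for each of the 4 main comparisons, the 8 called genes per direction with the smallest adjusted p and a mean log2 CPM of at least 1, up to 12 called members of the lists, App and Prnp, and the 2 members with the smallest p of each list called by camera. Unnamed predicted genes and pseudogenes were passed over, and some genes that the rule names are not reported here. Where none were called, the 5 genes with the smallest p were named. The other 4 comparisons have 4 genes per direction. Called list members beyond these were chosen after their values were seen.

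Reversal and overlap share the control mice, so both were set against 100 simulated treatment groups without effect and against 20 splits of the control mice between the comparisons. Chance was tested with 100 of the 126 splits of the 10 mice of a comparison, the real one included (for the mean of both compounds, 100 regroupings of 15 mice). Alternatives were RLE size factors, no filter, a stricter filter (1 CPM in 5 samples), DESeq2 1.42.0 and limma-voom with sample weights. Others were limma on log2 of the deposited FPKM plus 0.1 or 1 (mean FPKM of at least 0.5, or no filter), only the groups of a contrast, no mitochondrially encoded genes, a block for the replicate number, a 1.5-fold minimum, an unadjusted p, and leaving out each mouse. Added after seeing the data were the hypothalamus score or 4 scores (hypothalamus, striatum, thalamus and choroid plexus) as covariates, counts divided by 4, the combination without its 3 deepest libraries, the model comparison without wild type mice 2 and 3 and model mouse 1, and the median, call and gene counts of each single list without each mouse. Tested on simulated data with 200 changed genes, edgeR recovered 26.0%, 52.0% and 81.6% of changes of 1.25, 1.5 and 2-fold, with 5 false calls of 124. A donepezil group named in the study's design text has no samples here. No deposited sample was left out.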

Results

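RNA of the brain cortex was sequenced in 25 male mice aged 6 months, in 5 groups of 5 mice (n = 5 per group, each library from a separate mouse). The transgenic mice of the amyloid model carry a chimeric mouse and human App with the Swedish mutation under the mouse Prnp promoter, and deposit amyloid in the cortex. These mice, of strain B6C3, received vehicle (the model control), (-)-vestitol at 5 mg/kg, salviolone at 5 mg/kg, or both compounds at 2.5 mg/kg each, by daily intraperitoneal injection for 3 months. Vestitol is a plant isoflavan and salviolone a diterpenoid of Salvia species. The wild type mice were C57BL/6J and received vehicle. Total counts per library were 64008552 to 86378643 in wild type, 77772965 to 93132986 in the model control, 65336993 to 78331946 with vestitol, 59376320 to 72743740 with salviolone and 71606813 to 109776852 with the combination. Levels are given as CPM, counts scaled to the normalised library size, with mean ± SD over the 5 mice of a group. Log2 fold changes have their standard error (SE). A gene is called, and said to rise or fall, when its adjusted p was under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16515 genes.

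The transgene was checked first. App (chromosome 16, 84746573 to 84970654, mm39), the gene of the amyloid precursor protein, was at 4262 ± 354 CPM in the model control and 1672 ± 165 CPM in wild type, with a log2 fold change of 1.35 ± 0.08 (adjusted p = 6.4e-12). All 20 transgenic mice, from 3438 CPM up, lay above the highest wild type mouse, at 1800.1 CPM. Prnp (chromosome 2, 131751848 to 131780349), whose promoter drives the transgene, was at 1856 ± 146 CPM against 652 ± 40.5 CPM (log2 fold change 1.51 ± 0.07, adjusted p = 1.3e-13), and again all 20 transgenic mice exceeded every wild type mouse. With the compounds, App was at 4071 ± 311 CPM (vestitol), 4605 ± 437 CPM (salviolone) and 3758 ± 264 CPM (combination), and none of these differed from the model control in the test (adjusted p = 0.888, 0.591 and 0.104). The plot of App and of the hypothalamus list per mouse shows these levels.

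**Figure D1:**
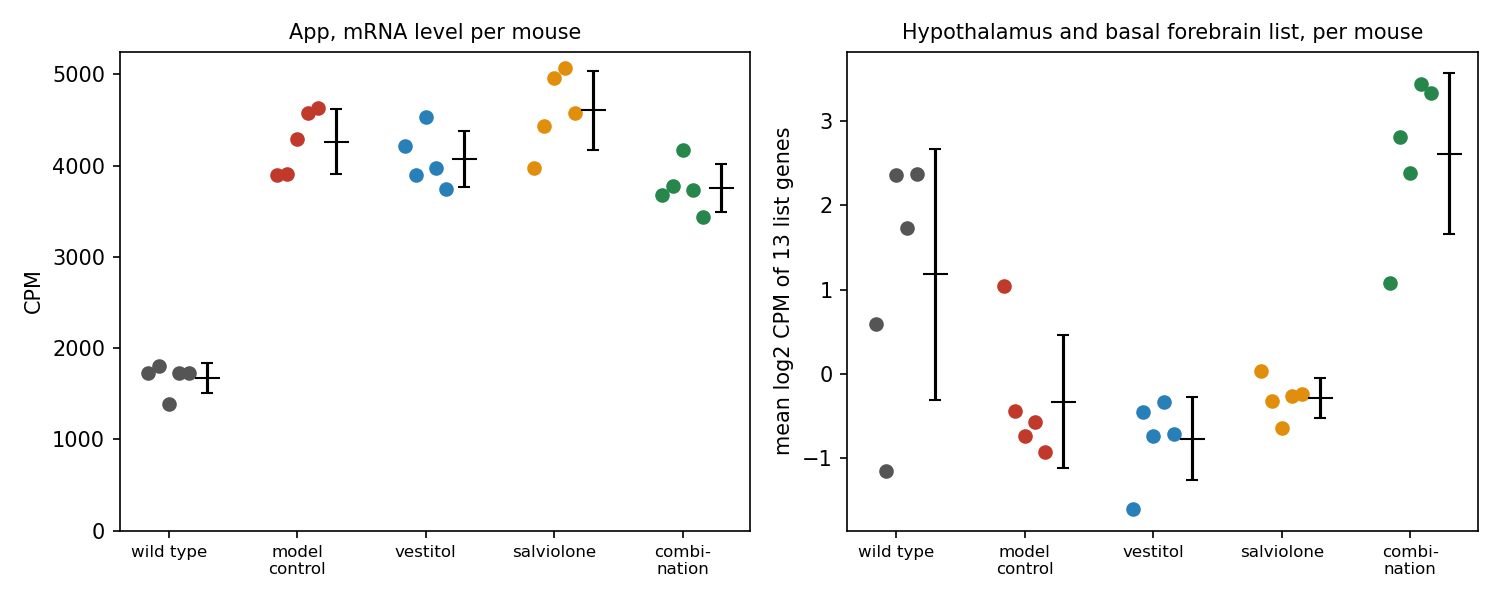
Left, App in CPM, and right, the mean log2 CPM of 13 genes of the hypothalamus and basal forebrain list, for each of the 25 mice. Dots are mice, and bars beside them are the group mean ± SD (n = 5). App separates the 20 transgenic from the 5 wild type mice, while the list score is 2.61 ± 0.96 in the combination group and -0.33 ± 0.78 in the model control.

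The comparison of the model control with wild type asks how the cortex of the amyloid model differs. Genes of microglia around amyloid plaques were higher in the model. Cst7, a cystatin that inhibits lysosomal proteases, was at 12.0 ± 3.13 CPM against 0.171 ± 0.0772 CPM, log2 fold change 6.10 ± 0.43 (n = 5), above the wild type mean in 5 of 5 mice. Itgax, which encodes the integrin CD11c, was at 8.11 ± 0.983 CPM against 0.393 ± 0.258 CPM, log2 fold change 4.36 ± 0.38. Trem2, a microglial lipid receptor, and its adaptor Tyrobp rose by log2 fold changes of 1.24 ± 0.16 and 1.20 ± 0.16, and the lysosomal genes Cd68, Ctsd and Ctsz by 0.94 ± 0.11, 0.71 ± 0.09 and 0.78 ± 0.10. Of the 28 genes in the list of plaque-associated microglia, 18 rose and 10 did not pass the test, with 20 raised when adjusted over the list alone (camera, adjusted p = 8.3e-32, and adjusted p = 0.00354 with an estimated correlation). It was the only list called both ways in this comparison. Among 14 homeostatic microglia genes, 1 rose and 13 did not pass the test, and the list was not called (adjusted p = 0.193).

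Some astrocyte, complement and innate immune genes also rose. Gfap, the intermediate filament of reactive astrocytes, was at 458 ± 45.2 CPM against 198 ± 46.7 CPM, log2 fold change 1.21 ± 0.15, and Serpina3n and Aspg rose as well (0.89 ± 0.15 and 0.72 ± 0.17), while the other 19 reactive astrocyte genes did not pass the test. Of 17 complement genes, 7 rose and 10 did not pass the test. Those that rose included C4b (log2 fold change 0.97 ± 0.15) and C1qa, part of the initiating complex, at 53.3 ± 4.76 CPM against 30.3 ± 3.72 CPM. Of 24 interferon-response genes, 8 rose and 16 did not pass the test, with 17 raised when adjusted over the list alone. Ifit2 (0.43 ± 0.11) was among the 8. The chemokine gene Cxcl10 (3.09 ± 0.55) and the receptor gene Tlr2 (1.00 ± 0.23) were the called members among 19 cytokine and NF-kB target genes. B2m (0.74 ± 0.16) and H2-T23 (0.62 ± 0.14) were those among 18 antigen presentation genes. Camera called the astrocyte, complement, interferon and cytokine lists at adjusted p = 0.0146, 0.00056, 1.3e-09 and 0.0177, and the calls were lost with an estimated correlation (adjusted p = 0.314, 0.297, 0.297 and 0.297 with an estimated correlation). Antigen presentation was not called (adjusted p = 0.0871). Leaving out single mice ended camera's call of cytokine (without wild type mouse 2) and reactive astrocyte (without wild type mouse 2). Medians moved by over 1.5 times for complement (0.34 without wild type mouse 4) and reactive astrocyte (0.07 without model mouse 4 and 0.27 without wild type mouse 3). Leaving out 1 mouse moved by over 1.5 times the number of raised reactive astrocyte genes (from 3 to 5 without wild type mouse 3) and raised interferon response genes (from 8 to 3 without model mouse 2 or wild type mouse 4, 1 without model mouse 5, 4 without wild type mouse 1 or 5 and 13 without wild type mouse 3). Raised interferon response genes over the list alone (from 17 to 6 without model mouse 5) changed too.

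Camera called 7 further lists, of which the first is the immediate-early genes. Of 24 immediate-early genes, 9 rose, 1 fell and 14 did not pass the test: Inhba (1.12 ± 0.16), Egr1 (0.70 ± 0.18) and Homer1 (0.61 ± 0.12) rose, with Arc at 499 ± 144 CPM against 211 ± 106 CPM, and Jun fell (-0.46 ± 0.14). In the pan-neuronal list the neurofilament genes Nefl, Nefm and Nefh rose (0.35 ± 0.05, 0.78 ± 0.11 and 0.70 ± 0.18), as did Snap25 and Rbfox3 (0.34 ± 0.09 and 0.21 ± 0.07), whereas Map2 and Uchl1 fell (-0.30 ± 0.07 and -0.30 ± 0.07). In the heat shock list Hspa4l, Dnaja1, Hsph1 and Chordc1 rose (0.34 ± 0.07, 0.24 ± 0.05, 0.33 ± 0.09 and 0.31 ± 0.08). In the unfolded protein response list Sdf2l1, Edem1, Atf4 and Xbp1 did (0.68 ± 0.17, 0.26 ± 0.06, 0.29 ± 0.08 and 0.35 ± 0.11). In the lysosome list the hydrolase genes Gusb and Hexa rose (0.60 ± 0.09 and 0.45 ± 0.07) with Lamp2 and Map1lc3b (0.24 ± 0.06 and 0.22 ± 0.05), and Wipi2 fell (-0.13 ± 0.04). Cycs, which encodes cytochrome c, Ndufa5, Ndufb5 and Atp5o rose in the nuclear oxidative phosphorylation list (0.22 ± 0.05, 0.27 ± 0.07, 0.19 ± 0.05 and 0.23 ± 0.08). The genes mt-Atp8 and mt-Co3 fell among 13 mitochondrially encoded genes (-0.78 ± 0.16 and -0.50 ± 0.11). These 7 lists had an adjusted p from 8.1e-08 (immediate-early genes) to 0.0218 (lysosome), and the calls were lost with an estimated correlation, at adjusted p from 0.297 to 0.489. Camera's call depended on single mice for lysosome (without model mouse 3). By over 1.5 times the median moved for lysosome (0.02 without model mouse 3, 0.05 without model mouse 4, 0.01 without wild type mouse 3 and 0.06 without wild type mouse 5), mitochondrially encoded (-0.31 without model mouse 1) and pan-neuronal (0.14 without model mouse 1 and 0.04 without wild type mouse 3). Counts of genes changed by over 1.5 times for lowered immediate-early genes (from 1 to 0 without model mouse 2 or 4 or wild type mouse 3, 4 or 5) and raised pan-neuronal genes (from 5 to 3 without model mouse 2 or 5 or wild type mouse 3 and 2 without wild type mouse 4). Raised heat shock genes (from 4 to 2 without wild type mouse 4) and raised unfolded protein response genes (from 4 to 7 without model mouse 1, 2 without model mouse 2, 4 or 5 or wild type mouse 1 and 1 without wild type mouse 4) changed too. Lowered lysosome genes (from 1 to 0 without model mouse 1, 2 or 4 or wild type mouse 1, 4 or 5) and raised nuclear oxidative phosphorylation genes (from 4 to 2 without model mouse 2, 1 without wild type mouse 1 and 7 without wild type mouse 2) changed too. Lowered mitochondrially encoded genes (from 2 to 7 without model mouse 1) changed too.

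Among the lowered genes with the smallest adjusted p were the deubiquitinase gene Usp11, at 155 ± 18.3 CPM against 228 ± 34.1 CPM, log2 fold change -0.55 ± 0.08, Mycl (-1.15 ± 0.17), Pnma3 (-0.88 ± 0.13), Gpsm1 (-0.61 ± 0.09), Susd2 (-0.73 ± 0.11) and Dnah5 (-0.95 ± 0.14). Markers of tissue next to the cortex moved as well. Hap1, abundant in hypothalamic neurons, was at 66.4 ± 30.4 CPM against 182 ± 77.9 CPM and Zcchc12 at 43.5 ± 23.2 CPM against 122 ± 50.9 CPM. With Baiap3 and Pomc they were the 4 genes that fell of 13 in the hypothalamus and basal forebrain list (median -1.49, 8 lowered when adjusted over the list alone, camera adjusted p = 0.00017, but adjusted p = 0.297 with an estimated correlation). Calb1, Fibcd1, Cpne7, Pkp2 and Nts fell in the hippocampus list (15 genes, median -0.42, adjusted p = 0.0146) and Aldh1a2 and Col1a2 in the meninges list (14 genes, median -0.52, adjusted p = 0.00139), but not with an estimated correlation (adjusted p = 0.297 and 0.468). Pomc was at 85.8 CPM in wild type mouse 3, whose library also held Gh and Prl, and at most 3.49 CPM in the others. The hypothalamus score, the mean log2 CPM of its list, was 1.18 ± 1.49 in wild type and -0.33 ± 0.78 in the model. Wild type mouse 2, at -1.15, lay below the model mean, and model mouse 1, at 1.04, above the other model mice. With single mice left out, camera did not call hippocampus (without model mouse 3). The list median moved by over 1.5 times for hippocampus (-0.24 without wild type mouse 3) and hypothalamus (-2.49 without model mouse 1). Counts moved by over 1.5 times for lowered hypothalamus genes (from 4 to 7 without wild type mouse 2) and lowered hypothalamus genes over the list alone (from 8 to 5 without model mouse 5 and 4 without wild type mouse 5). Lowered hippocampus genes (from 5 to 3 without model mouse 3 or wild type mouse 3 or 5, 2 without model mouse 4 or 5 and 0 without wild type mouse 4) and lowered meninges genes (from 2 to 0 without model mouse 2 or 3 or wild type mouse 3 or 4, 1 without model mouse 4 or 5 or wild type mouse 1 and 4 without wild type mouse 2) changed too.

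Myelin genes had a median of 0.29 (camera adjusted p = 0.00056, but adjusted p = 0.564 with an estimated correlation), and Gjb1 alone of 16 rose (0.49 ± 0.15). Leaving out 1 mouse moved by over 1.5 times the number of raised myelin genes (from 1 to 0 without model mouse 1, 2, 4 or 5 or wild type mouse 1 or 4, 9 without model mouse 3 and 2 without wild type mouse 2). Other tissue and cell markers were not called as lists: choroid plexus (median 0.88), blood cells (1.22), striatum (-0.07), thalamus (0.01), ependyma (-0.05), endothelium (0.14), mural cells (-0.14), astrocytes (0.03) and oligodendrocyte precursors (-0.15), with adjusted p from 0.0704 to 0.968. The lists for amyloid processing and clearance, tau kinases, excitatory synapse, inhibitory neurons, cholinergic system, calcium signalling, cholesterol synthesis, circadian clock, glucocorticoid response, antioxidant response and ribosomal proteins were not called either, with medians between -0.17 (cholinergic system) and 0.10 (calcium signalling) and adjusted p of 0.242 or more. Genes known to vary between C57BL/6J and C3H had a median of 0.04, and Nnt, whose C57BL/6J allele is disrupted, was at 33.7 ± 5.05 CPM against 24.7 ± 0.792 CPM (log2 fold change 0.45 ± 0.16, adjusted p = 0.0706, not called).

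In all, 1913 of 16515 genes were called between model and wild type, 887 raised and 1026 lowered, and the median size of their log2 fold changes was 0.40. The count was 285 with the hypothalamus score as a covariate, of which the list of plaque-associated microglia held 14. Over the 1913 genes the median size went from 0.40 to 0.32 with that score and the median SE from 0.102 to 0.109, and 100% had the sign they had before. The count was 349 when only these 10 mice entered the fit, 954 without wild type mouse 4, 1194 without model mouse 2 and 2928 without wild type mouse 2. Strain and genotype differ together between these groups.

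**Figure D2:**
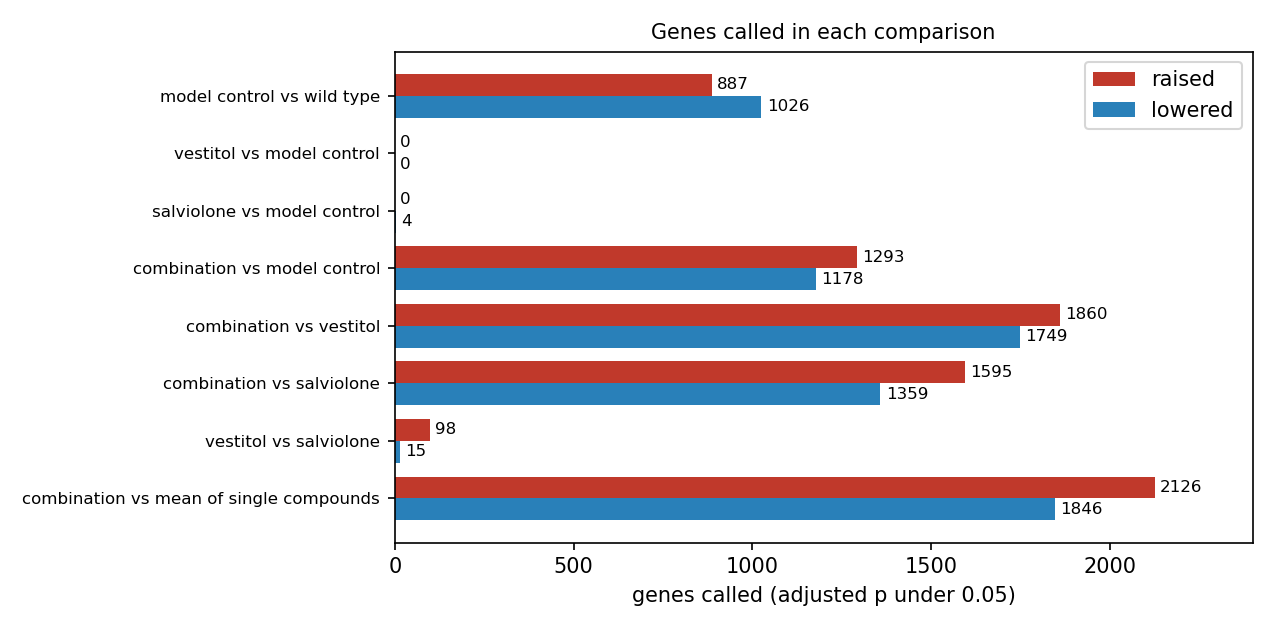
Number of genes raised and lowered in each of the 8 comparisons (edgeR's quasi-likelihood test, adjusted p under 0.05, 16515 genes tested, n = 5 mice per group). Each single compound against the model control gave 0 or 4 genes, and each comparison with the combination 2471 or more.

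The comparison of vestitol with the model control asks what the compound alone changed. The genes with the smallest p were Usp2, a deubiquitinase gene with circadian expression (106 ± 9.59 CPM against 83.7 ± 4.13 CPM, log2 fold change 0.34 ± 0.07, n = 5), Alkbh1 (-0.38 ± 0.08), the Notch modifier gene Lfng (0.41 ± 0.08), the splicing factor gene Sf3b1 (0.19 ± 0.04) and Cib2 (-0.40 ± 0.09), and none was called (adjusted p = 0.251 for each). The 13 mitochondrially encoded genes had a median log2 fold change of 0.32, with mt-Co3 at 0.53 ± 0.11 and mt-Nd3 at 24.2 ± 1.44 CPM against 17.8 ± 4.08 CPM, and 10 were raised when adjusted over the list alone. Choroid plexus genes were lower, by a median of -1.70, with 12 of 15 lowered when adjusted over the list alone. Their F5 and Kl were at 0.544 ± 0.461 CPM against 3.58 ± 4.35 CPM and 2.19 ± 0.313 CPM against 6.70 ± 5.49 CPM. Camera called both lists (adjusted p = 1.3e-17 and 7.8e-12), but adjusted p = 0.269 and 0.304 with an estimated correlation. The choroid plexus score was 2.87 and 1.59 in model mice 4 and 5, against -0.32 to 0.37 in the other 3. Medians moved by over 1.5 times for choroid plexus (-1.0 without model mouse 4). Counts of genes changed by over 1.5 times for raised mitochondrially encoded genes over the list alone (from 10 to 6 without model mouse 4) and lowered choroid plexus genes over the list alone (from 12 to 0 without model mouse 4, 1 without vestitol mouse 1 and 6 without vestitol mouse 3).

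Camera called a further 10 lists with its preset correlation and none with an estimated one. Higher were glucocorticoid-responsive genes (median 0.20, with 6 raised when adjusted over the list alone), plaque-associated microglia (0.15), homeostatic microglia (0.08) and circadian clock genes (0.05). Lower were immediate-early genes (-0.24), meninges (-0.57), heat shock (-0.12), nuclear oxidative phosphorylation (-0.04), thalamus (-0.51) and the hypothalamus list (-0.76), all with adjusted p of 0.469 or more with an estimated correlation. Example members were Tsc22d3, a glucocorticoid-induced leucine zipper gene (97.3 ± 9.82 CPM against 71.5 ± 5.77 CPM), the clock output gene Dbp (80.2 ± 17.1 CPM against 54.5 ± 9.24 CPM), Arntl (-0.27 ± 0.09), Hspa8 (-0.27 ± 0.09), Jun (-0.33 ± 0.14), Dcn (-1.16 ± 0.32), Mertk (0.22 ± 0.09) and Axl (0.15 ± 0.06). Among microglial genes, Cst7 and Trem2 differed from the model control by 0.38 ± 0.31 and 0.07 ± 0.16, with 95% intervals of -0.26 to 1.02 and -0.26 to 0.39, and were not called. Striatum, hippocampus, blood cell and strain-variable lists had medians of 0.09, -0.09, 0.35 and 0.12 and were not called. The glucocorticoid score was 5.46 in vestitol mouse 5, against 4.51 to 4.72 in the other 4, and the hypothalamus score 1.04 in model mouse 1, against -0.93 to -0.44. Camera's call depended on single mice for clock (without model mouse 1 or 2 or vestitol mouse 1 or 3), homeostatic microglia (without model mouse 5 or vestitol mouse 5) and hypothalamus (without model mouse 1 or vestitol mouse 1 or 5). Plaque-associated microglia (without vestitol mouse 5) and thalamus (without model mouse 2) lost it too. By over 1.5 times the median moved for clock (0.02 without model mouse 1 or vestitol mouse 1, 0.09 without model mouse 3 or vestitol mouse 5, 0.08 without vestitol mouse 2 or 3 and 0.10 without vestitol mouse 4), glucocorticoid (0.10 without vestitol mouse 5) and heat shock (-0.21 without vestitol mouse 1 and -0.07 without vestitol mouse 2). Homeostatic microglia (0.13 without model mouse 1 or vestitol mouse 1 or 2, 0.16 without model mouse 3 and 0.05 without vestitol mouse 3), hypothalamus (-0.10 without model mouse 1) and immediate-early genes (-0.15 without model mouse 3 and -0.44 without vestitol mouse 1) moved too. Meninges (-0.32 without model mouse 4), nuclear oxidative phosphorylation (-0.06 without model mouse 1 or vestitol mouse 4) and thalamus (-0.08 without model mouse 2 and -0.94 without vestitol mouse 2) moved too. Counts moved by over 1.5 times for raised glucocorticoid genes over the list alone (from 6 to 0 without model mouse 1, 3 or 5 or vestitol mouse 5, 3 without model mouse 4 and 2 without vestitol mouse 3). In edgeR's quasi-likelihood test 0 of 16515 genes were called (lowest adjusted p = 0.251). There were 1249 genes at an unadjusted p under 0.05, against 826 by chance, and DESeq2 called 45.

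The comparison of salviolone with the model control asks the same of the second compound. Called were 4 genes, all lowered: Fnbp1l, an actin regulator gene (119.5 ± 8.38 CPM against 148 ± 6.33 CPM, log2 fold change -0.31 ± 0.06, n = 5), the collagen gene Col11a1 (14.0 ± 3.01 CPM against 23.3 ± 4.52 CPM, log2 fold change -0.73 ± 0.13), the mucin gene Muc6 (9.93 ± 1.20 CPM against 15.3 ± 1.54 CPM, log2 fold change -0.63 ± 0.11) and Marf1 (214 ± 7.56 CPM against 248 ± 6.61 CPM, log2 fold change -0.21 ± 0.04), each at an adjusted p of 0.0487 and each lower in 5 of 5 mice than every control mouse. The 13 mitochondrially encoded genes lay below the control, by a median of -0.46, with mt-Nd5 at 583 ± 74.1 CPM against 805 ± 147 CPM and mt-Co2 at 274 ± 49.1 CPM against 376 ± 52.6 CPM, and all 13 were lowered when adjusted over the list alone. Striatum genes were lower by a median of -0.40, 9 of 15 when adjusted over the list alone, with Rxrg at 21.6 ± 4.11 CPM against 36.5 ± 9.84 CPM and Syndig1l at 32.0 ± 3.73 CPM against 48.3 ± 8.72 CPM. Camera called both lists (adjusted p = 4.0e-23 and 2.7e-10), but adjusted p = 0.102 and 0.335 with an estimated correlation.

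The further 11 lists that camera called with its preset correlation were not called with an estimated one (adjusted p of 0.281 or more). Higher were glucocorticoid-responsive genes (0.18), plaque-associated microglia (0.18), ribosomal proteins (0.05), myelin genes (0.14), lysosome (0.06), meninges (0.34) and nuclear oxidative phosphorylation (0.03). Lower were choroid plexus (-0.84), calcium signalling (-0.06), heat shock (-0.13) and endothelium (-0.13). Members with the smallest p included Mt1 (0.26 ± 0.07), Rpl13 (0.21 ± 0.05), Calb1 (-0.40 ± 0.11), Ryr3 (-0.37 ± 0.11), Hspd1 (-0.24 ± 0.07), Csf1 (0.25 ± 0.10) and Mbp (0.24 ± 0.12), none called. The hippocampus, thalamus, blood cell and strain-variable lists had medians of -0.03, 0.30, 0.49 and 0.10, and the hypothalamus list -0.60, none of them called. Leaving out single mice ended camera's call of calcium signalling (without salviolone mouse 1), choroid plexus (without model mouse 4 or 5 or salviolone mouse 2 or 3) and endothelium (without model mouse 2 or 3 or salviolone mouse 1, 3 or 4). Heat shock (without model mouse 2, 3 or 5 or salviolone mouse 3 or 5), meninges (without model mouse 2 or 3 or salviolone mouse 2 or 3) and myelin (without model mouse 3) lost it too. Nuclear oxidative phosphorylation (without model mouse 1, 3 or 4 or salviolone mouse 1 or 4) and ribosomal proteins (without model mouse 2) lost it too. Medians moved by over 1.5 times for calcium signalling (-0.09 without model mouse 1), choroid plexus (-0.02 without model mouse 4 and -1.32 without salviolone mouse 1) and glucocorticoid (0.10 without salviolone mouse 5). Heat shock (-0.08 without salviolone mouse 5), meninges (0.18 without salviolone mouse 2) and myelin (0.01 without model mouse 3) moved too. Nuclear oxidative phosphorylation (0.02 without salviolone mouse 4) and ribosomal proteins (0.03 without model mouse 2) moved too. Cst7 and Trem2 differed from the control by 0.38 ± 0.31 and 0.18 ± 0.16, with 95% intervals of -0.26 to 1.02 and -0.15 to 0.51. In all 1893 genes had an unadjusted p under 0.05 and DESeq2 called 129. The 4 calls lie at the threshold: with RLE size factors or without a filter on low counts edgeR called 0, and leaving out single mice gave between 0 and 30.

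The comparison of the combination with the model control asks what both together changed. Some genes of cholinergic and GABAergic neurons rose. Ache, which encodes acetylcholinesterase, was at 74.0 ± 13.4 CPM against 41.2 ± 2.59 CPM, log2 fold change 0.84 ± 0.10 (n = 5), and Chat, which makes acetylcholine, rose by 1.34 ± 0.24. Gad2, which makes GABA, was at 348 ± 46.0 CPM against 212 ± 30.0 CPM, log2 fold change 0.72 ± 0.10, and Slc32a1, the vesicular GABA transporter gene, at 177 ± 21.8 CPM against 115 ± 7.73 CPM, log2 fold change 0.63 ± 0.09. Among activity-regulated genes Egr3 was at 137 ± 11.6 CPM against 228 ± 39.9 CPM, log2 fold change -0.74 ± 0.14, Dusp6 at 49.5 ± 2.96 CPM against 79.5 ± 12.7 CPM, log2 fold change -0.68 ± 0.12 and Arc at a log2 fold change of -1.37 ± 0.33. Susd2, Vat1, Bex1, Maged1, Cygb and Gpr83 were among the raised genes with the smallest adjusted p (0.97 ± 0.11, 0.98 ± 0.12, 0.71 ± 0.09, 0.36 ± 0.05, 0.58 ± 0.08 and 0.75 ± 0.10). Vip, the kinase gene Rock2, Rgs6, Strbp, Dnajc21, Ccng1, Mical2 and the potassium channel gene Kcnk4 fell (-0.83 ± 0.10, -0.49 ± 0.06, -0.70 ± 0.09, -0.61 ± 0.08, -1.10 ± 0.15, -0.92 ± 0.13, -0.83 ± 0.12 and -0.96 ± 0.14).

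Markers of tissue below the cortex rose together with these genes. Of 13 hypothalamus and basal forebrain genes, 9 rose and 4 did not pass the test (median 2.88), with Hap1 at 205 ± 21.9 CPM against 66.4 ± 30.4 CPM and Zcchc12 at 159 ± 26.9 CPM against 43.5 ± 23.2 CPM. Of 15 striatum genes, 11 rose and 4 did not pass the test (median 0.63), with the enkephalin gene Penk at 405 ± 69.0 CPM against 205 ± 33.6 CPM and Six3 at 17.8 ± 2.80 CPM against 7.91 ± 2.52 CPM. The hypothalamus score was 2.61 ± 0.96 in the combination group and -0.33 ± 0.78 in the model control, and the striatum score 6.00 ± 0.26 and 5.29 ± 0.23. When adjusted over the list alone, 11 hypothalamus and 14 striatum genes were raised. Camera called both lists (adjusted p = 4.1e-08 and 3.8e-10), but adjusted p = 0.330 and 0.330 with an estimated correlation. The thalamus (median -0.10), hippocampus (0.30), meninges (0.31), choroid plexus (-0.74), ependyma (-0.40), blood cell (-1.05) and strain-variable (0.07) lists were not called.

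Other neuronal lists held changes alongside the rise in the hypothalamus score. Of 16 cholinergic genes, 7 rose, 2 fell and 7 did not pass the test, the falls being the receptor genes Chrm3 and Chrna5. Of 24 immediate-early genes, 13 fell and 11 did not pass the test. Of 28 excitatory synapse genes, 1 rose, 10 fell and 17 did not pass the test, the rise being Camk2b (0.17 ± 0.06), with the NMDA receptor gene Grin2a at 250.2 ± 29.0 CPM against 379 ± 35.7 CPM and Snap25 at 1174 ± 85.0 CPM against 1669.8 ± 132 CPM. Of 17 inhibitory neuron genes, 6 rose, 6 fell and 5 did not pass the test: Sst, Reln, Calb2 and Tac1 rose with Gad2 and Slc32a1, and those that fell included Vip, Pvalb, Npy and Cck. In the calcium signalling list (25 genes, 3 rose, 10 fell and 12 did not pass the test) the channel genes Cacna1h, Ryr3 and Cacna1c rose. Camera called the first 3 of these lists (adjusted p = 0.0122, 6.7e-10 and 0.00022, but adjusted p = 0.330, 0.445 and 0.459 with an estimated correlation) and neither inhibitory neurons nor calcium signalling (adjusted p = 0.304 and 0.140). By over 1.5 times the median moved for cholinergic system (0.16 without combination mouse 3). Leaving out 1 mouse moved by over 1.5 times the number of lowered cholinergic system genes (from 2 to 1 without model mouse 3 or 5 or combination mouse 3, 4 or 5) and raised excitatory synapse genes (from 1 to 0 without model mouse 1, 2, 4 or 5 or combination mouse 1, 4 or 5). Lowered excitatory synapse genes (from 10 to 6 without combination mouse 4 or 5) and lowered inhibitory neuron genes (from 6 to 3 without model mouse 2, 3 or 5 or combination mouse 1 and 2 without combination mouse 4) changed too. Lowered calcium signalling genes (from 10 to 6 without model mouse 2) changed too.

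Outside neuronal lists, some ribosomal protein and oligodendrocyte precursor genes rose and some mitochondrially encoded, interferon and clock genes fell. Of 52 ribosomal protein genes, 21 rose, 1 fell and 30 did not pass the test (median 0.14, with Rplp1 at 0.29 ± 0.06 and Rpl32 at 0.23 ± 0.05, and Rpl22 the one that fell). Of 10 oligodendrocyte precursor genes, 4 rose and 6 did not pass the test, the rises being C1ql1, Pdgfra, Lhfpl3 and Gpr17 (0.95 ± 0.17, 0.40 ± 0.10, 0.68 ± 0.20 and 0.39 ± 0.12). Of the 13 mitochondrially encoded genes, 6 fell and 7 did not pass the test, with mt-Atp6 at 266 ± 20.7 CPM against 372 ± 59.8 CPM and mt-Co2 at -0.41 ± 0.10. Of 24 interferon genes, 4 fell and 20 did not pass the test, the falls being Ifit1, Ifit2, Parp14 and Ifih1 (-1.02 ± 0.25, -0.45 ± 0.11, -0.76 ± 0.21 and -0.59 ± 0.18). Of 17 clock genes, 4 fell and 13 did not pass the test, the falls being Hlf, Nr1d2, Bhlhe40 and Npas2 (-0.74 ± 0.13, -0.35 ± 0.11, -0.42 ± 0.14 and -0.19 ± 0.07). Of 18 antigen presentation genes, 1 fell and 17 did not pass the test, the fall being H2-T23 (-0.71 ± 0.14). Camera called these 6 lists at adjusted p from 5.8e-07 (ribosomal proteins) to 0.0374 (antigen presentation), but adjusted p = 0.459 or more with an estimated correlation. With single mice left out, camera did not call antigen presentation (without model mouse 3 or 5 or combination mouse 1, 2 or 5) and clock (without model mouse 3, 4 or 5 or combination mouse 4 or 5). Counts of genes changed by over 1.5 times for raised ribosomal protein genes (from 21 to 11 without model mouse 2 or combination mouse 1, 12 without combination mouse 4 and 13 without combination mouse 5) and lowered ribosomal protein genes (from 1 to 0 without model mouse 1, 3, 4 or 5 or combination mouse 2, 3 or 4). Raised oligodendrocyte precursor genes (from 4 to 2 without model mouse 4) and lowered mitochondrially encoded genes (from 6 to 3 without model mouse 1) changed too. Lowered interferon response genes (from 4 to 2 without model mouse 5) and lowered clock genes (from 4 to 1 without model mouse 2 or combination mouse 1 or 4 and 2 without model mouse 3, 4 or 5 or combination mouse 5) changed too. Lowered antigen presentation genes (from 1 to 3 without combination mouse 3 and 2 without combination mouse 4) changed too.

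Plaque-associated microglia genes were not called as a group. Lpl alone of 28 rose (0.51 ± 0.17, adjusted p = 0.0437, 0 when adjusted over the list alone). Counts moved by over 1.5 times for raised plaque-associated microglia genes (from 1 to 0 without model mouse 2, 4 or 5 or combination mouse 1, 2 or 4). The list median was -0.04 and the camera adjusted p was 0.492. Cst7, Itgax and Trem2 differed from the control by -0.12 ± 0.31, -0.29 ± 0.31 and -0.16 ± 0.16, with 95% intervals of -0.76 to 0.51, -0.93 to 0.36 and -0.48 to 0.17, against rises of 6.10, 4.36 and 1.24 in the model. Gfap differed by -0.05 ± 0.14 (-0.35 to 0.25). C1ra and C1s1 fell in the complement list (-1.60 ± 0.32 and -1.15 ± 0.31). Sorl1 fell while Clu and Aplp1 rose in the amyloid processing list (-0.45 ± 0.10, 0.20 ± 0.05 and 0.18 ± 0.04). Leaving out 1 mouse moved by over 1.5 times the number of lowered amyloid processing and clearance genes (from 1 to 2 without model mouse 1, 3 or 5). Neither list was called, nor were the homeostatic microglia, reactive astrocyte, astrocyte, myelin, cytokine, lysosome, tau kinase, cholesterol synthesis, antioxidant, heat shock, unfolded protein, glucocorticoid, endothelial, mural, pan-neuronal or nuclear oxidative phosphorylation lists (adjusted p of 0.0759 or more). The plot of microglial and astrocyte genes shows all 4 comparisons.

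**Figure D3:**
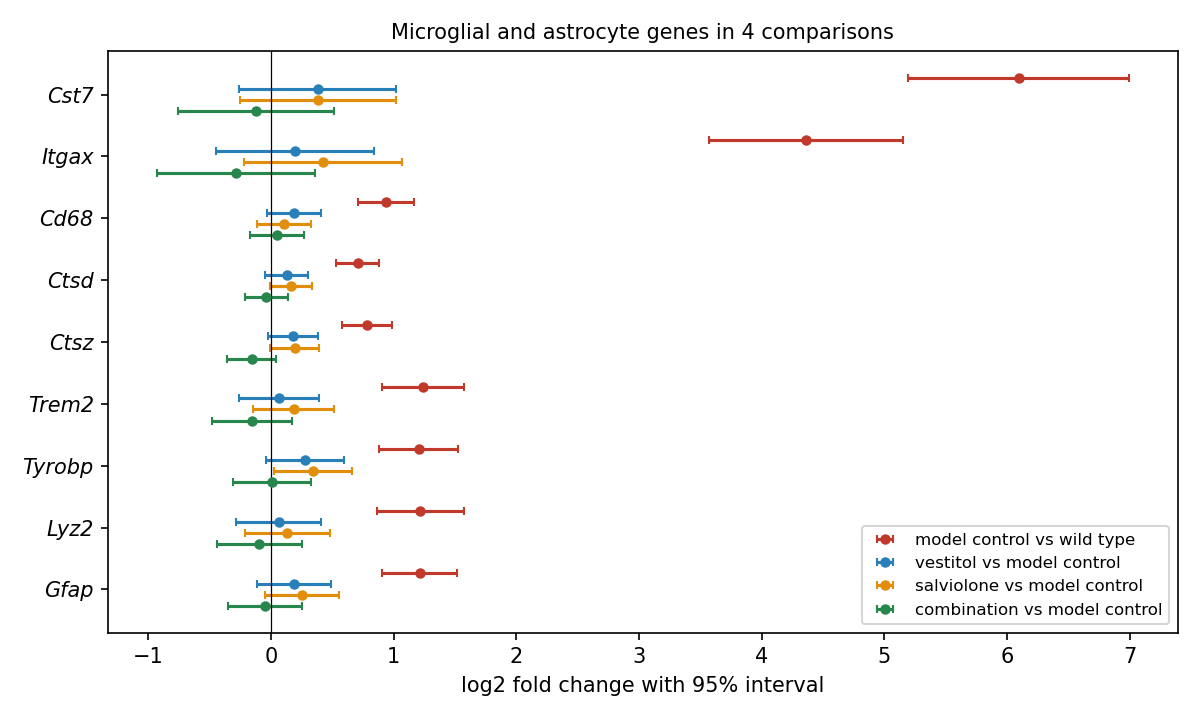
Log2 fold changes of 9 microglial and astrocyte genes with 95% intervals in the model control against wild type and in each treatment against the model control (n = 5 mice per group). All 9 lie above 0 in the model, from 0.71 (Ctsd) to 6.10 (Cst7). With the combination every interval includes 0.

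In all, 2471 genes were called between the combination and the model control, 1293 raised and 1178 lowered, with a median size of 0.41 on the log2 scale. Without a covariate 4618 genes had an unadjusted p under 0.05 and DESeq2 called 2865. With the hypothalamus score as a covariate edgeR called 0. Over the 2471 genes the median size was 0.41 without and 0.21 with it, the median SE 0.10 and 0.14, and 95.5% of the genes had the sign they had before. The combination libraries 3, 4 and 5 were the deepest of the series, and without them 914 genes were called.

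How far each treatment moved the genes that differ in the model was measured over the 1913 genes called between model and wild type. With the combination 96.1% of them had the opposite sign, against 52.1% with vestitol and 50.2% with salviolone. Because the control mice enter both sides, simulated groups without any effect gave 65.8% on average (95% of them 37.0% to 88.6%), a range that holds both single compounds. The combination lay above all 100 simulations. With the control mice split between the 2 comparisons, the means over 20 splits were 89.4%, 38.7% and 35.6%. Called in both and opposite were 1051 genes with the combination, among them Susd2, Hap1, Zcchc12, Nefl and Egr3. In the same direction were 2. Independent lists would share 144 opposite and 143 alike, but the shared control mice push called genes towards opposite signs. No simulated or split value was computed for these counts. Across genes, the covariance of the 2 log2 fold changes was -0.149 with the combination against -0.0601 in the simulations, and -0.0260 and -0.0254 with the single compounds. Of 41 immune list genes called in the model, 33 had the opposite sign with the combination, 5 of them called. Of 18 plaque-associated microglia genes 14 did, 0 of them called. Medians of the 41 were 0.93 in the model and -0.13. Neither set had a simulated value or was tested against other genes. In the hypothalamus list all 4 genes called in the model had the opposite sign with the combination, 3 of them called, with medians of -1.93 in the model and 1.75 with the combination. The hypothalamus score was 1.18 ± 1.49 in wild type, -0.33 ± 0.78 in the model control and 2.61 ± 0.96 with the combination.

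Genes shared between the treatments were counted. No gene called with vestitol could be shared, since edgeR called 0 there (1249 at an unadjusted p under 0.05, 45 by DESeq2). Of the 4 genes lowered by salviolone, 2 were also lowered by the combination, where independent lists would share 0.285 and simulated groups without effect 0.0300 on average, and with the control mice split the mean was 0.200. The log2 fold changes of vestitol and salviolone had a covariance across genes of 0.0492, against 0.0536 from the shared control mice alone. At an unadjusted p under 0.05 these 2 shared 338 genes in the same direction and 27 in opposite ones, where simulated groups without effect shared 153 and split control mice left 77.8. For vestitol and salviolone against the combination the covariance was 0.0141 and 0.0466, neither above the simulated value. These pairs shared 213 and 527 genes in the same direction at that p (229 and 244 in opposite ones), with the same simulated number and 71.0 and 172 with split control mice.

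Vestitol and salviolone, which differ in their whole carbon skeleton, were compared at the same dose of 5 mg/kg. All 13 mitochondrially encoded genes were higher with vestitol. Among those with the smallest adjusted p, mt-Co3, a cytochrome c oxidase subunit, was at 182 ± 17.6 CPM against 94.2 ± 16.3 CPM, log2 fold change 0.95 ± 0.12 (n = 5). The complex I subunit mt-Nd5 was at 1007 ± 89.2 CPM against 583 ± 74.1 CPM, log2 fold change 0.79 ± 0.10, mt-Co2 at 455 ± 35.5 CPM against 274 ± 49.1 CPM and mt-Atp6 at 476 ± 30.4 CPM against 266 ± 43.2 CPM. The list median was 0.77, all 13 also passed when adjusted over the list alone, and camera called the list (adjusted p = 6.3e-69, and adjusted p = 0.00028 with an estimated correlation), the one list so called here. Mitochondrially encoded genes took 0.787% ± 0.0327 of all counts with vestitol and 0.493% ± 0.0988 with salviolone, beside 0.554% ± 0.0488 with the combination, 0.677% ± 0.102 in the model control and 0.707% ± 0.0600 in wild type (SD, n = 5 each). The nuclear genes Cox6b1, of the same oxidase, and Taco1, which activates its mt-Co1 translation, were lower with vestitol (-0.22 ± 0.05 and -0.37 ± 0.08), as were Slc24a3 and Zic5 (-0.39 ± 0.08 and -1.10 ± 0.20).

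**Figure D4:**
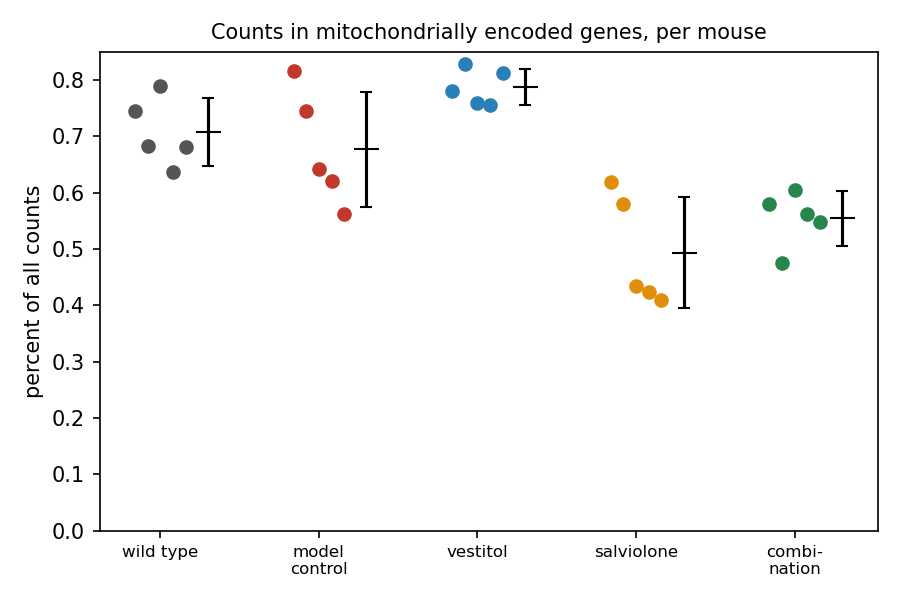
Share of all counts in mitochondrially encoded genes, in percent, for each mouse, with the group mean ± SD (n = 5). The vestitol mice lie between 0.755% and 0.829%, and the salviolone mice between 0.409% and 0.620%.

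Camera called 10 more lists between the single compounds, with its preset correlation only: striatum (median 0.54), calcium signalling (0.08) and endothelium (0.14) higher with vestitol. Lower were meninges (-0.71), nuclear oxidative phosphorylation (-0.10), immediate-early genes (-0.29), ribosomal proteins (-0.08), thalamus (-0.81), choroid plexus (-0.97) and lysosome (-0.05), each list at an adjusted p of 0.122 or more with an estimated correlation. Plaque-associated microglia genes had a median of -0.05, and Cst7 and Trem2 differed by -0.00 ± 0.31 and -0.12 ± 0.16, with 95% intervals of -0.64 to 0.63 and -0.45 to 0.21. The hypothalamus, hippocampus, blood cell and strain-variable medians were -0.21, -0.11, -0.15 and -0.06, not called. Leaving out single mice ended camera's call of choroid plexus (without salviolone mouse 1) and endothelium (without vestitol mouse 5). Medians moved by over 1.5 times for choroid plexus (-0.26 without salviolone mouse 1 and -1.47 without vestitol mouse 5), endothelium (0.09 without vestitol mouse 5 or salviolone mouse 1) and immediate-early genes (-0.47 without vestitol mouse 1). In all 113 genes were called, 98 higher and 15 lower with vestitol. The count was 12 with 4 tissue scores as covariates (median size from 0.39 to 0.40, median SE from 0.0856 to 0.108, 100% with the same sign), 41 with these 10 mice alone, and between 14 (without salviolone mouse 3) and 204 (without salviolone mouse 1) when single mice were left out.

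The combination was then set against each single compound, the total dose being 5 mg/kg in all 3 groups. Against vestitol, the kinase gene Rock2 (149 ± 8.59 CPM against 229 ± 14.9 CPM, log2 fold change -0.62 ± 0.06), the ubiquitin ligase gene Ube3a (57.7 ± 4.94 CPM against 90.7 ± 5.48 CPM, log2 fold change -0.65 ± 0.07) and the proteasome activator gene Psme4 (-0.59 ± 0.07) were lower. Vat1, Cd200, Susd2 and Maged1 were higher (1.09 ± 0.12, 0.70 ± 0.08, 0.96 ± 0.11 and 0.41 ± 0.05). Against salviolone, the transcription factor genes Dach1 (24.7 ± 2.84 CPM against 9.40 ± 1.39 CPM, log2 fold change 1.39 ± 0.14) and Meis2 (146 ± 14.9 CPM against 81.0 ± 8.52 CPM, log2 fold change 0.85 ± 0.09), both strongly expressed in striatal lineages, were higher with Ankrd63 and Vat1 (1.19 ± 0.12 and 1.12 ± 0.12). The transcription factor gene Nfix (167 ± 21.6 CPM against 368 ± 15.4 CPM, log2 fold change -1.14 ± 0.13), Nrep, Kcnk4 and Olfml2b (-1.20 ± 0.14, -1.15 ± 0.14 and -1.19 ± 0.14) were lower. App and Prnp, chosen here after their values were seen, were lower with the combination than with salviolone (-0.29 ± 0.07 and -0.21 ± 0.07, adjusted p = 0.00637 and 0.0309), and against vestitol they were not called (-0.12 ± 0.07 and -0.11 ± 0.07).

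The tissue lists moved in both comparisons. Of 13 hypothalamus genes, 11 rose against vestitol and 10 against salviolone (medians 3.68 and 3.01), and of 15 striatum genes 9 and 14 (medians 0.56 and 1.05). Of 24 immediate-early genes 10 and 14 fell, with Jun higher in both. Falls were also called for clock genes, 6 and 6 of 17, and excitatory synapse genes, 12 and 10 of 28. Mitochondrially encoded genes fell against vestitol (12 of 13, median -0.67) and had a median of 0.11 against salviolone, not called. Plaque-associated microglia genes had medians of -0.23 and -0.27, with Ank, Ctsz, Ctsb and Csf1 lowered in both (-0.34 ± 0.10 and -0.35 ± 0.10 for Ctsz). Camera called 15 and 12 lists, and 0 with an estimated correlation (lowest adjusted p 0.233 and 0.0818). Against vestitol with single mice left out, camera did not call immediate-early genes (without vestitol mouse 1) and plaque-associated microglia (without vestitol mouse 3 or 5 or combination mouse 2). By over 1.5 times the median moved for immediate-early genes (-0.19 without vestitol mouse 1) and plaque-associated microglia (-0.15 without vestitol mouse 5). Against salviolone it did not call excitatory synapse (without salviolone mouse 3 or combination mouse 4 or 5) and plaque-associated microglia (without combination mouse 2). The list median moved by over 1.5 times for clock (-0.08 without salviolone mouse 5) and plaque-associated microglia (-0.17 without combination mouse 2). Against vestitol the counts moved by over 1.5 times for raised striatum genes (from 9 to 4 without combination mouse 5 and 5 without vestitol mouse 1 or 3) and lowered immediate-early genes (from 10 to 6 without combination mouse 1 and 5 without vestitol mouse 1 or combination mouse 3). Lowered clock genes (from 6 to 3 without combination mouse 4) and lowered plaque-associated microglia genes (from 4 to 2 without vestitol mouse 3 or 5 or combination mouse 1) changed too. Against salviolone they did for lowered clock genes (from 6 to 3 without combination mouse 1, 4 or 5) and lowered excitatory synapse genes (from 10 to 6 without combination mouse 4 or 5). In all 3609 genes were called against vestitol (1860 raised, 1749 lowered) and 2954 against salviolone (1595 raised, 1359 lowered). With the hypothalamus score as a covariate the counts were 14 and 12, with the median size going from 0.40 to 0.23 and from 0.44 to 0.25 and the median SE from 0.0993 to 0.153 and from 0.103 to 0.143.

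The combination holds a lower dose of each compound, so effects that add up linearly with dose would give the mean of the single-compound groups on the log2 scale. Magel2, an imprinted gene expressed in the hypothalamus, was at 14.2 ± 4.87 CPM with the combination, 1.17 ± 0.795 CPM with vestitol and 0.891 ± 0.243 CPM with salviolone (log2 fold change 3.80 ± 0.36 against the mean), and the receptor gene Glp1r at 7.33 ± 3.76 CPM, 0.666 ± 0.265 CPM and 0.661 ± 0.190 CPM (3.46 ± 0.34). Vat1 and Susd2 rose (1.11 ± 0.10 and 0.91 ± 0.09), and Rgs6, Nfix, Olfml2b and Kcnk4 fell (-0.74 ± 0.08, -1.11 ± 0.12, -1.12 ± 0.12 and -1.09 ± 0.12). Of 13 hypothalamus genes 11 rose (median 3.68) and of 15 striatum genes 14 (median 0.86), while 14 of 24 immediate-early and 13 of 28 excitatory synapse genes fell. Meninges, hippocampus, thalamus, choroid plexus, blood cell and strain-variable medians were 0.33, 0.15, 0.07, 0.32, -1.34 and -0.01, not called. Camera called 13 lists, and 0 with an estimated correlation, where the lowest adjusted p was 0.185. Leaving out 1 mouse moved by over 1.5 times the number of lowered excitatory synapse genes (from 13 to 8 without combination mouse 4). In all 3972 genes differed from the mean of the single compounds, 2126 raised and 1846 lowered. At an unadjusted p under 0.05 there were 5820, and DESeq2 called 4356. With the hypothalamus score as a covariate edgeR called 0, the median size going from 0.38 to 0.20 and the median SE from 0.0872 to 0.141.

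In every list that camera called in the 8 comparisons, the median, the mean and the test had one sign. Among lists not called these differed in sign as follows. For the model control against wild type they did in ribosomal proteins, cholesterol synthesis, ependyma and thalamus. For vestitol against the model control they did in amyloid processing and clearance, tau and tau kinases, antioxidant response, unfolded protein response, astrocytes, mural cells, ependyma and strain-variable between C57BL/6J and C3H. For salviolone against the model control they did in reactive astrocytes, amyloid processing and clearance, tau and tau kinases, astrocytes and hippocampus. For the combination against the model control they did in autophagy and lysosome, unfolded protein response and thalamus. For the combination against vestitol they did in inhibitory neurons, autophagy and lysosome, antioxidant response, unfolded protein response and mural cells. For the combination against salviolone they did in homeostatic microglia, cholinergic system, nuclear oxidative phosphorylation, unfolded protein response, calcium signalling and choroid plexus. For vestitol against salviolone they did in reactive astrocytes, complement, inhibitory neurons, tau and tau kinases, unfolded protein response, astrocytes and blood cells. For the combination against the mean of the single compounds they did in homeostatic microglia, antioxidant response and unfolded protein response.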

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

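The tests of other splits were planned. Those of tissue, depth, strain and RNA recovery were set up after the patterns had been seen, but before their own results, and those of the plaque-associated microglia under the hypothalamus score, of exchanged labels and of the 4 scores for mitochondrially encoded genes were chosen only after the results were seen, as were the permuted range used for the model and the minimum number of transcripts used for RNA recovery.

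The combination differed from the model control in 2471 genes, and 1 of 100 splits of the 10 mice, the real one, gave as many (highest other 156). Chance is thus unlikely, though 100 splits cannot show a share below 1 in 100. With the 2 less deep combination libraries alone, 100% of the called genes kept their sign. This cannot decide on depth, since these libraries and the same control mice had also served to pick the genes. More hypothalamic and ventral forebrain tissue in the samples may account for the pattern: slopes on the hypothalamus score within the wild type, vestitol and salviolone groups gave the sign of 91.0% of called genes outside the lists, but scores permuted within groups gave up to 91.1% at the upper end of their 95% range, and 66.7% had it without wild type mouse 2 and 61.1% within the vestitol and salviolone groups alone. With that score as a covariate the median size of the called changes went from 0.41 to 0.21 and its SE from 0.10 to 0.14, and the calls ended because the change shrank and the SE rose. An effect of the treatment and a difference in dissection cannot be told apart for these genes.

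The model control differed from wild type in 1913 genes, as many in 2 of 100 splits, the real one included (highest other 2574, next 1768). Chance is thus unlikely but not excluded. The higher split exchanged model mouse 1 and wild type mouse 2 and points to a structure of the samples. Exchanged labels are excluded, since App in model mouse 1 was at 3897 CPM, above every wild type mouse. Less hypothalamic tissue in the model is excluded for plaque-associated microglia, 13 of whose 18 called genes were also called with the hypothalamus score as a covariate, but stays open for the other genes: 285 genes were called with it, and over all 1913 the median size went from 0.40 to 0.32 and the median SE from 0.102 to 0.109, so that calls ended mainly as the change shrank, and 100% had the same sign, but these genes were picked by the same difference. Slopes within the treated groups gave the sign of 42.8%, under the lower bound written beforehand, yet permuted scores gave 28.4% to 70.9%, so that bound was wrong. Strain may account for part, as 13.4% of called genes had a called neighbour (shuffled 9.99 to 12.8%), but the ratio to shuffled positions, 1.18, was 1.17 for the combination, where strain does not differ. Genotype and strain differ together and cannot be told apart for the genes other than App and Prnp.

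Mitochondrially encoded genes were higher with vestitol than with salviolone, and 113 genes were called in all. As many came in 1 of 100 splits, the real one (highest other 25), so chance is unlikely. Depth is excluded as the whole cause, since 10 of 13 were called with log2 total counts as a covariate, at a median of 0.74 against 0.77 without. Tissue as far as these 4 scores measure it is excluded as the whole cause: with them as covariates the median was 0.94 and its SE 0.152 against 0.112 without, and 9 of 13 were called, while the other 4 went from a median of 0.63 to 0.74 and an SE of 0.123 to 0.180, so that their calls ended as the SE rose. RNA recovery could not be tested, since only Snhg11 of the nuclear-retained transcripts chosen for it was tested, and its log2 fold change of 0.0913 met the bound for exclusion on 1 transcript alone. With RNA recovery open and further causes untested, an effect of the compounds is only a hypothesis.

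Other splits of the mice gave as many genes in 5 of 100 for salviolone against the model control (real 4, highest other 206), so chance is not excluded there. For vestitol the real count was 0 (highest other 2), so 100 of 100 splits gave as many by construction. The splits thus say nothing about vestitol. EdgeR's 0 for vestitol stands beside 1249 genes at an unadjusted p under 0.05 and 45 by DESeq2. The split with 206 genes exchanged model mice 3 and 5 with salviolone mice 1 and 2 and points to a structure of the samples. Against the combination, 1 of 100 gave as many for vestitol (real 3609, highest other 270), salviolone (2954 and 3) and the mean of both (3972 and 2). Chance is thus unlikely for these.

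Single mice also stood apart from the other 4 of their group, with a gap to the nearest mouse above 0.71 of the group's range (Dixon's ratio). Chance gives this in about 1 of 20 groups, or 27 of the 540 tested, and 45 were found. The ratios follow by mouse, with list scores as mean log2 CPM.

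Wild type mouse 2 was low in Cxcl10 (0.755), Hap1 (0.787), Pnma3 (0.719) and Zcchc12 (0.785). Wild type mouse 3 was low in transgene check score (0.736) and App (0.836) and high in reactive astrocytes score (0.877), interferon response score (0.732), unfolded protein response score (0.782) and Hexa (0.831). Wild type mouse 5 was high in Dnaja1 (0.711).

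Model mouse 1 was low in Cst7 (0.741) and high in hypothalamus and basal forebrain score (0.751), Dnah5 (0.818), Pnma3 (0.810) and Vat1 (0.816). Model mouse 2 was high in total counts (0.914). Model mouse 3 was low in amyloid processing and clearance score (0.845), myelinating oligodendrocytes score (0.738), Ifit2 (0.771) and Cldn11 (0.753) and high in Igf1 (0.775). Model mouse 4 was low in Cd68 (0.733) and Jun (0.713). Model mouse 5 was low in striatum score (0.861), Mertk (0.714) and Tsc22d3 (0.754).

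Vestitol mouse 1 was low in Slc6a13 (0.816) and high in pan-neuronal score (0.876) and Jun (0.719). Vestitol mouse 2 was high in thalamus score (0.802). Vestitol mouse 3 was low in total counts (0.765) and Atp5o (0.724) and high in Susd2 (0.802). Vestitol mouse 4 was low in Alkbh1 (0.773) and Olfml2b (0.750). Vestitol mouse 5 was high in glucocorticoid-responsive score (0.770) and astrocytes score (0.818).

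Salviolone mouse 1 was low in calcium signalling score (0.763). Salviolone mouse 4 was low in glucocorticoid-responsive score (0.717). Salviolone mouse 5 was high in circadian clock score (0.752).

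Combination mouse 2 was low in mitochondrially encoded score (0.749) and mt-Atp6 (0.823). Combination mouse 3 was low in immediate-early genes score (0.758) and high in Rgs6 (0.747).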

How the results depend on the processing

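The fits with covariates, with counts divided by 4, without the deep combination libraries and without 3 doubted mice of the model comparison, and single lists without each mouse, were chosen after the results were seen; the other alternatives were planned. Where a value given here moved, the cause was not tested unless stated.

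Across tools, scalings and filters the counts of the model control against wild type (1913) and of the combination against the model control (2471), vestitol, salviolone and the mean of both stayed within 1.5 times, DESeq2, limma-voom, FPKM and the replicate block included, and counts divided by 4 did too. Salviolone against the model control (4) was at 0 with RLE size factors, without mitochondrially encoded genes, without a filter, with the stricter filter, with limma-voom and with limma on unfiltered FPKM, at 1 with only its groups, at 29 with the replicate block and at 129 with DESeq2. Vestitol against the model control (0) was at 45 with DESeq2, and vestitol against salviolone (113) at 286. With only the groups of the contrast, the model comparison gave 349 and vestitol against salviolone 41, with fewer mice for the spread. Mice with the same replicate number in different groups showed no pairing: their mean correlation was 0.000366 over 50 pairs, none above 0.1.

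With the hypothalamus score as a covariate, edgeR called 285 genes in the model, 8 for salviolone, 0 for the combination against the model control (without the covariate 4618 at an unadjusted p under 0.05 and 2865 by DESeq2), 14 and 12 against vestitol and salviolone, and 0 against their mean. Over the genes called without it the median size went from 0.40 to 0.32 in the model, 0.47 to 0.47 for salviolone and 0.41 to 0.21 for the combination. With 4 scores the counts were 95 in the model, 0 for salviolone, 0, 0, 0 and 0 for the 4 comparisons of the combination, and 12 for vestitol against salviolone. The median size then went from 0.40 to 0.29 (SE 0.102 to 0.112) in the model, 0.47 to 0.43 (0.0843 to 0.108) for salviolone, 0.41 to 0.16 (0.101 to 0.155), 0.40 to 0.21 (0.0993 to 0.162), 0.44 to 0.18 (0.103 to 0.194) and 0.38 to 0.17 (0.0872 to 0.169) for the combination, and 0.39 to 0.40 (0.0856 to 0.108) for vestitol against salviolone, where the calls ended as the SE rose. Without combination libraries 3, 4 and 5 the combination differed from the model control in 914 genes, with fewer mice. Without wild type mice 2 and 3 and model mouse 1 the model comparison gave 2754. A 1.5-fold minimum left 595 (model), 2 (salviolone), 760 (combination), 1166, 1070 and 1193 (combination against vestitol, salviolone and their mean) and 24 (vestitol against salviolone). An unadjusted p under 0.05 gave 4267, 1249 (vestitol), 1893, 4618, 5525, 4881 and 1935, by construction.

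With an estimated correlation camera called 1 list in the model, 1 between the compounds and 0 in the other 6 comparisons. Fry called 14 in the model, 0 for vestitol, 2 for salviolone, 12 for the combination, 16, 11 and 19 for its comparisons with vestitol, salviolone and their mean, and 6 between the compounds. Of the lists camera called, 8 of 16, 11 of 12, 9 of 13, 3 of 11, 5 of 15, 7 of 12, 3 of 11 and 3 of 13 lost the call or moved their median by over 1.5 times without some single mouse, in the order model, vestitol, salviolone, combination, its comparisons with vestitol and salviolone, vestitol against salviolone and the mean, and none changed sign. At an unadjusted p under 0.05 vestitol and salviolone shared 338 genes, vestitol and the combination 213, and salviolone and the combination 527, against 153 in simulated groups and 77.8, 71.0 and 172 with split controls, and 27, 229 and 244 had opposite signs. Independent lists of the real sizes would share 71.6, 175 and 264 in the same direction. Called genes shared by the last pair numbered 0.200 with split controls. With split controls the shares of model genes with the opposite sign under vestitol and salviolone turned from above to below 50% (38.7% and 35.6%). Prnp with salviolone, not called, changed sign, at -0.00242 with 4 scores and -0.00429, -0.0257, -0.00563 and -0.00948 without model mice 1 and 2 and salviolone mice 3 and 4 (highest 0.0481 without salviolone mouse 1), and App with the combination at 0.00748 with the hypothalamus score.

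Leaving out single mice gave 954 to 2928 genes in the model (954 without wild type mouse 4, 1194 without model mouse 2, 2928 without wild type mouse 2), 0 to 2 for vestitol (2 without model mouse 1), 1812 to 2588 for the combination, 2863 to 3429 and 2327 to 2856 against vestitol and salviolone, and 3228 to 3906 against their mean. Salviolone ran from 0 to 30: 0 without any of model mice 1 to 4 or salviolone mice 2 and 3, 16 without model mouse 5, 30 and 2 without salviolone mice 1 and 4. Vestitol against salviolone ran from 14 to 204: 39, 35 and 40 without vestitol mice 1, 2 and 4, and 204, 14, 30 and 24 without salviolone mice 1, 3, 4 and 5. Called lists numbered 15 to 19, 11 to 14, 9 to 15, 9 to 12, 12 to 17, 8 to 13, 11 to 15 and 11 to 14 in the order model, vestitol, salviolone, combination, its comparisons with vestitol and salviolone, vestitol against salviolone and the mean. App and Prnp in the model ran from 1.29 to 1.38 and 1.48 to 1.55. Of 1950 values of named genes under the alternatives chosen before the data were examined, apart from leaving out mice, 1866 kept direction and side of the threshold, 57 lost and 27 gained a call. Of 1830 with a mouse left out, 1745 did so, 69 lost and 12 gained a call, and 4 changed sign.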

Other observations

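The test of a segregating background was set up after the levels had been seen and before its own result.

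Transcripts known from the anterior pituitary were abundant in 1 library. In wild type mouse 3 Gh, the growth hormone gene, was at 5314 CPM, Prl at 399 CPM, Cga at 226 CPM, Pomc at 85.8 CPM, Lhb at 28.8 CPM and Tshb at 4.61 CPM. The next highest of the 25 libraries were at 3.07 CPM for Gh and 0.352 CPM for Prl.

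The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty lay at different levels among the transgenic mice. Kdm5d was at 44.9 to 49.3 CPM in wild type, and at 50.7, 48.8, 48.8, 43.8, 47.3 and 47.8 CPM in model mouse 2, vestitol mice 4 and 5, salviolone mouse 1 and combination mice 4 and 5. The remaining transgenic mice were at 65.5 to 94.9 CPM. Nnt ran from 22.8 to 51.8 CPM in the transgenic mice and from 23.7 to 25.7 CPM in wild type. A hypothesis is that the B6C3 background segregates among the transgenic mice and may carry more than 1 Y chromosome. It would make neighbouring genes vary together within the transgenic groups. The mean correlation of neighbouring genes within 1 Mb was 0.0487 there (SD 0.0186 over 4 groups) and 0.0503 in wild type, a difference of -0.00160, smaller than that spread, so the hypothesis stays open.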
